A study of Homo sapiens with 2 samples.

How the data were processed

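Strand-specific mRNA libraries of C4-2B MDVR cells were sequenced (KAPA Stranded mRNA-Seq kit, on total RNA isolated with TRIzol, per the labels' protocols), 1 library from cells given DMSO and 1 from cells given 20 µM Indocin for 3 days in the presence of 20 µM enzalutamide. The deposited values were FPKM (fragment numbers scaled by transcript length and by library size) per gene symbol with a status, per the file headers. The submitters' processing notes name bcl2fastq, TopHat, Cufflinks, StringTie and Cuffnorm and the builds GRCh37 and hg19. The role and version of each tool, the gene annotation and the strand setting are not given in the sources used here. Both tables listed the same 25268 symbols, each on 1 line, and every line had the status OK. Of these, 7752 were listed at 0 in the DMSO library and 7515 in the Indocin library, 6841 of them in both. A 0 can be a failed estimate, so it was read as a listed value and not as absence. The reference annotation used here belongs to another build, so no coordinates were taken from it.

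FPKM values are not read counts, so no count test was run, and the number of reads per library was not recovered. FPKM summed to 617510 in the DMSO library and 583096 in the Indocin library, the 10 highest genes held 13.6% and 11.4% of the sum, and the median FPKM of the tested genes was 12.5 and 12.3. Relative depth was read from the steps of low values: for 1262 genes with a mean under 0.05 FPKM, the ratio of the libraries was compared, within 1%, with a common factor times ratios of small whole numbers, and the factor that took most genes was 1.014.

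The following choices were made before the data were examined. The log2 ratio was log2((Indocin FPKM + 1)/(DMSO FPKM + 1)). Genes entered with a mean of the 2 libraries of at least 1 FPKM. Symbols of short RNA genes (microRNAs, small nucleolar, Cajal body and nuclear RNAs and similar) were left out by the start of the symbol, because FPKM is unstable at lengths near the fragment length. This rule took 2066 symbols, among them 26 of long host transcripts of microRNAs, of which 7 had a mean of at least 1 FPKM. A gene was counted at 2-fold, and a member of a gene list at 1.5-fold, both by the log2 ratio of FPKM + 1. With 1 library per group there was no test, and percentiles describe these 2 libraries and not the conditions.

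For each of 38 gene lists written from general knowledge, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, drawn with replacement from tested genes in the same of 20 bins of mean expression. A list outside the middle 95% was described as standing apart, and lists with under 5 measured members got values only. The 10 lists that answered the comparison included androgen response, steroid synthesis, ATF4 targets, ER chaperones, heat shock proteins, proteasome, ubiquitin system, DNA replication and mitosis, and some genes and 1 list are not reported here. Other lists covered lipid metabolism, stress, signalling, cell-type markers and RNA quality. Of 30 lists with a percentile 16 stood apart, 8 on the higher side and 8 on the lower, where 1.5 would by chance if genes were independent. Genes of a list are regulated together and some belong to several lists, so this chance number is too low.

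The genes named were the 15 highest and 15 lowest log2 ratios with a mean of at least 2 FPKM, 23 genes fixed whatever their value, and up to 4 members of each list with the largest ratios in size. Genes named as exceptions to a count, and genes of 5 lists added later, were chosen after their values were seen. Close paralogs (the AKR1C, UGT2B, TUBA3, HSPA1 and histone genes among them) can share reads, and their values are uncertain.

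Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter or a mean of at least 5 FPKM, ratios centred on their median, libraries scaled to the same upper quartile or to the same sum over all genes but short RNA genes, short RNA genes kept, a 1.5-fold threshold for genes and list members held by another list left out. The noncoding RNA BCYRN1, not caught by the symbol rule, stayed in that sum (43986 FPKM in the DMSO library and 26889 FPKM in the Indocin library). The same-sum values therefore depend in part on this 1 gene. The common sum was also larger than either FPKM sum while the pseudocount stayed at 1, so the pseudocount weighed less in these values. A trend of the log2 ratio over transcript length, GC content and mean expression was removed, and microRNA host genes were kept, as alternatives added after seeing the data. The trend was removed for the ATF4, DNA replication, androgen response and fatty acid synthesis lists only. Percentiles of the other lists, those of glycolysis, ER chaperones and ribosomal proteins among them, were not checked against it. Length and GC content came from a GRCh38 annotation by gene symbol, for 93.8% of tested genes. The calculation was tested on simulated data for 2 libraries at the means of Indocin against DMSO: all 143 genes changed 4-fold with a mean of at least 5 FPKM were recovered past 2-fold, and 3.67% of 300 random lists of unchanged genes lay outside the middle 95%. The simulated noise was of a chosen size and independent for each gene. It was far smaller than a 4-fold change, so recovery was near certain. The share of random lists does not hold for lists of genes regulated together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.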

Results

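The data were RNA-seq libraries of C4-2B MDVR cells, a castration-resistant prostate cancer line of the LNCaP lineage that is resistant to the antiandrogen enzalutamide and was kept in 20 µM enzalutamide. The 2 libraries analysed here were 1 from cells given the vehicle DMSO and 1 from cells given 20 µM Indocin, both for 3 days. Indocin is indomethacin, an inhibitor of the cyclooxygenases PTGS1 and PTGS2 that also inhibits AKR1C3, an enzyme of androgen synthesis. Each group had 1 library, so no difference below has a replicate check, and no test, p-value or error across cultures could be given. The values were FPKM per gene symbol, and the absolute read depth was unknown. Among 1262 genes with a mean under 0.05 FPKM, 41.6% had an Indocin to DMSO ratio within 1% of 1.014 times a ratio of small whole numbers, against a median of 1.90% for other factors, so 1 fragment was worth about the same in both libraries. FPKM values of at least 1 were listed for 11935 genes in the DMSO library and 12078 in the Indocin library. The noncoding RNA BCYRN1 alone held 7.12% of the summed FPKM in the DMSO library and 4.61% in the Indocin library, and cytosolic ribosomal protein genes held 23.8% and 25.2%. The sum was smaller in the Indocin library (583096 against 617510) and the median log2 ratio of ribosomal protein genes was 0.01. Their larger share there thus does not mean higher ribosomal protein values.

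The comparison asked how the transcriptome of these enzalutamide-resistant cells differed after Indocin. The gene with the highest ratio was CHAC1, which encodes a glutathione-degrading enzyme and stood at 5.07 FPKM in the DMSO library and 88.4 FPKM in the Indocin library (log2 ratio 3.88). S100P, a calcium-binding protein, followed at 9.12 and 138.5 FPKM (3.79), and FGF21, a secreted metabolic hormone, at 0.293 and 13.3 FPKM (3.47). FAM129A (3.28), the cystine transporter SLC7A11 (3.05), the mTORC1 inhibitor DDIT4 (2.77) and asparagine synthetase, ASNS (2.69), came next. The glycine transporter SLC6A9 (2.45), the long noncoding RNA LINC01133 (2.39) and KLHDC7B (2.24) were also among the 15 highest, the last from 0.0573 FPKM in the DMSO library. The order depended on the pseudocount. With 0.1 FPKM, FGF21 (5.10) and KLHDC7B (4.70) lay above CHAC1 (4.10), and with 5 FPKM, S100P (3.35) lay above CHAC1 (3.21). Unless another pseudocount is named, log2 ratios are on the log2(FPKM + 1) scale, Indocin over DMSO, which understates the fold of genes with low values. Genes counted as past a fold were counted on the same scale. A gene with low values can therefore pass a fold in FPKM alone and not be counted.

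At the lower end, APLN, which encodes the peptide apelin, stood at 11.4 FPKM in the DMSO library and 4.69 FPKM in the Indocin library (-1.13). The phosphatase DUSP2 stood at 100.4 and 48.1 FPKM (-1.05), the meiotic recombinase DMC1 at 3.81 and 1.20 FPKM (-1.13), and the alpha-tubulin TUBA3D at 9.66 and 3.79 FPKM (-1.16). TUBA3D is nearly identical in sequence to TUBA3E (-1.05), named after its value was seen, so the reads of the pair may have been divided between them. Short of 2-fold on the log2(FPKM + 1) scale were the transcription factors RUNX1 (-0.96) and HES7 (-0.92), the water and glycerol channel AQP3 (-0.89), RPRML (-0.89), endothelin 2, EDN2 (-0.90), and C11orf82 (-0.85). With a pseudocount of 0.1 FPKM, RUNX1 (-1.105), HES7 (-1.14), RPRML (-1.06) and EDN2 (-1.16) were past 2-fold. AQP3 (-0.90) and C11orf82 (-0.93) were not. Cell cycle genes made up the other names among the 15 lowest: CCNE2 (-0.93), CDC25A (-0.92), CDK1 (-0.90), RRM2 (-0.85) and MCM10 (-0.84).

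Of 11961 genes with a mean of at least 1 FPKM, 90 were at least 2-fold higher in the Indocin library and 5 at least 2-fold lower. With a pseudocount of 5 FPKM these counts were 41 and 0, and with a pseudocount of 0.1 FPKM they were 132 and 22. At 1.5-fold, 262 genes were higher and 90 lower, so 74.4% of these lay on the higher side. That share was 84.7% (321 higher, 58 lower) with both libraries scaled to the same upper quartile and 84.8% (390 higher, 70 lower) with both scaled to the same sum, BCYRN1 included. The same-sum setting also lessened the weight of the pseudocount, so its counts mix both changes. The share was 69.0% (420 higher, 189 lower) with a pseudocount of 0.1 FPKM and 68.1% (277 higher, 130 lower) with short RNA genes kept, where the share at 2-fold was 71.0% against 94.7%. The median log2 ratio of all tested genes was -0.03, with quartiles of -0.15 and 0.11, and 97.1% of genes lay within 1.5-fold. Of the 90 genes at least 2-fold higher, 25 belonged to the list of ATF4 targets and 5 to the lists of fatty acid or cholesterol synthesis. Of the 90 genes at least 1.5-fold lower, 14 belonged to the lists of DNA replication or mitosis.

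**Figure D1:**
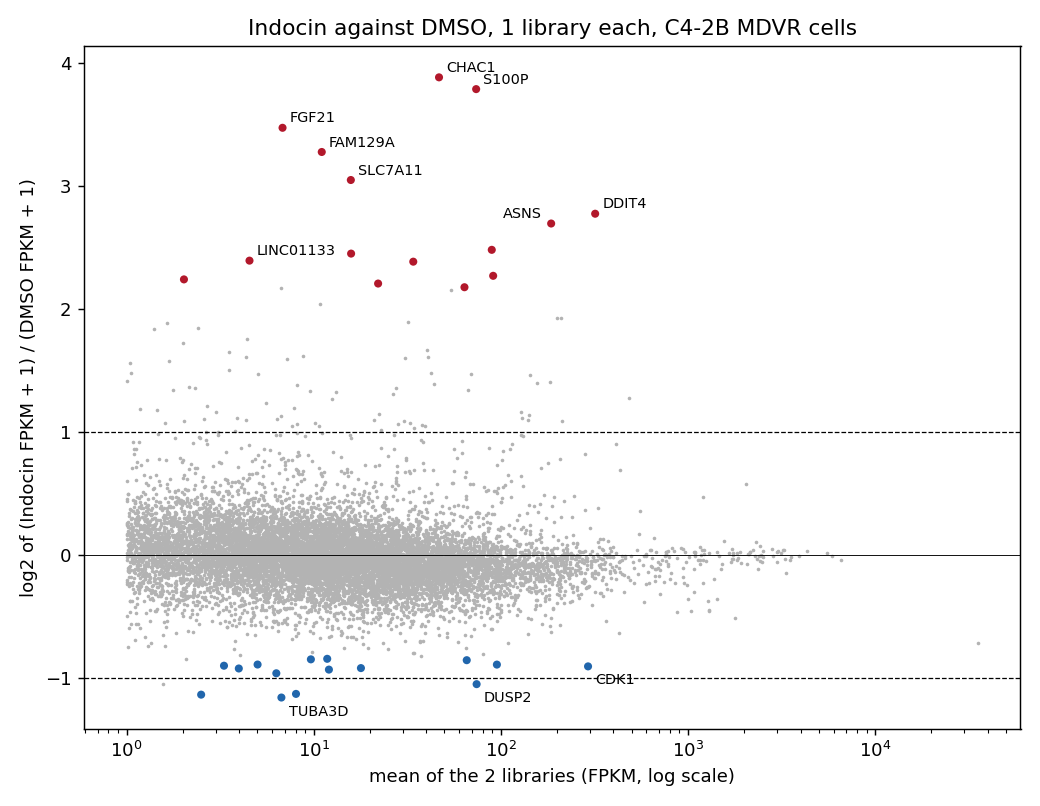
Each point is 1 of 11961 tested genes, with the mean FPKM of the 2 libraries on a log axis and the log2 ratio of Indocin over DMSO on the other axis, the 15 highest (red) and 15 lowest (blue) genes with a mean of at least 2 FPKM in colour and dashed lines at 2-fold. CHAC1 lies highest at 3.88 and TUBA3D lowest at -1.16, with 90 genes on or above the upper dashed line and 5 on or below the lower one.

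Targets of ATF4, the transcription factor of the integrated stress response, were higher in the Indocin library as a group. ATF4 itself stood at 283.9 FPKM in the DMSO library and 689 FPKM in the Indocin library (1.28). Its partners and targets DDIT3, also called CHOP, (22.5 and 105.4 FPKM, 2.18), ATF3 (10.3 and 57.8 FPKM, 2.38) and the pseudokinase TRIB3 (26.5 and 152.4 FPKM, 2.48) were higher, as were the stress-induced mTORC1 regulator SESN2 (7.22 and 37.0 FPKM, 2.21) and PCK2, mitochondrial phosphoenolpyruvate carboxykinase (30.6 and 151.4 FPKM, 2.27). ASNS stood at 49.0 and 322.6 FPKM and DDIT4 at 80.7 and 557.9 FPKM. All 34 genes of the list, which includes ATF4 itself, were measured and had ratios above 0 under every scaling tried. Of these, 33 were at least 1.5-fold higher and 25 at least 2-fold higher, the exception at 1.5-fold being the phosphatase subunit PPP1R15A (0.18). The list median was 1.47 (quartiles 1.01 and 2.20), at percentile 100 among the medians of 10000 random lists of the same size and matched expression.

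Chaperones of the endoplasmic reticulum (ER) differed far less between the libraries. HSPA5, the main ER chaperone, stood at 324.6 FPKM in the DMSO library and 355 FPKM in the Indocin library (0.13). The degradation factor HERPUD1 (79.3 and 145 FPKM, 0.86) and the transcription factor XBP1 (151.3 and 261.4 FPKM, 0.78) were the 2 of 31 members at least 1.5-fold higher, none was as much lower, and SEL1L (0.52) and ATF6 (0.43) came next. Of the 31 members 17 were above 0 and 14 below (23 and 8 with the same upper quartile or the same sum). The lowest were SDF2L1 (-0.24), DERL3 (-0.23) and MANF (-0.19). The list median was 0.00 (quartiles -0.07 and 0.15), against -0.06 for random lists, at percentile 98.3.

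Heat shock proteins and their co-chaperones were lower in the Indocin library. HSP90AA1 stood at 791.3 and 635.1 FPKM (-0.32), HSPH1 at 55.3 and 40.7 FPKM (-0.43), and DNAJA1 at 246.7 and 188 FPKM (-0.39). HSPA1B stood at 73.2 and 44.5 FPKM (-0.71), while its nearly identical neighbour HSPA1A was listed at 0.0709 and 0.0904 FPKM (0.03), so reads of this pair may not be assigned reliably. Of 21 measured members 1, HSPA1B, was at least 1.5-fold lower and none as much higher. All 21 ratios were below 0 as deposited, and 20 under each rescaling, where HSPD1 changed sign. The median was -0.31, at percentile 0.

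Genes of protein degradation lay close to the median of all genes. Among 38 proteasome genes none differed by 1.5-fold, the furthest being PSME3 (-0.29), PSMD3 (-0.20) and ADRM1 (-0.17), and the median was -0.06, at percentile 75.8. Among 40 genes of the ubiquitin system none differed by 1.5-fold either. STUB1, which encodes the ligase CHIP, stood at 97.3 FPKM in the DMSO library and 89.7 FPKM in the Indocin library (-0.12), NEDD4 had a ratio of 0.45, SIAH2 of 0.35 and UBE2T of -0.40. The ubiquitin median was -0.05, at percentile 63.5. Both medians changed sign, to 0.02 and 0.02, with the libraries scaled to the same upper quartile, and stayed inside the middle 95% of random lists.

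Several androgen-induced genes were lower in the Indocin library, among them EAF2 (22.3 FPKM in the DMSO library and 14.2 FPKM in the Indocin library, -0.61), CHRNA2 (3.92 and 2.37 FPKM, -0.55) and SLC45A3 (217.6 and 153 FPKM, -0.51). The kallikrein KLK3, which encodes prostate-specific antigen, stood at 71.7 and 58.1 FPKM (-0.30), KLK2 at 128.4 and 93.7 FPKM (-0.45), FKBP5 at 225.3 and 172.1 FPKM (-0.39) and TMPRSS2 at 105.3 and 109 FPKM (0.05). Of 45 measured androgen response genes 31 had ratios below 0 and 14 above, the highest being ACSL3 (0.49) and SAT1 (0.41). On the log2(FPKM + 1) scale 2, EAF2 among them, were at least 1.5-fold lower and none as much higher. CHRNA2 was past 1.5-fold in FPKM alone. With either the same upper quartile or the same sum, 29 were below 0 and none was 1.5-fold lower. The median was -0.16 (quartiles -0.37 and 0.02), at percentile 0.04. It was -0.09 with the same upper quartile or the same sum, at percentiles 0.04 and 0.03, and -0.0927 over the 42 members with a length and GC value after removal of a trend over transcript length, GC content and expression, added after seeing the data, at percentile 0.77. Before that removal these 42 had a median of -0.16.

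Among 5 measured androgen-repressed genes the median was -0.22, at percentile 2.77, with no member past 1.5-fold. The list lay inside the middle 95%, near its edge, and outside it with a pseudocount of 0.1 FPKM, the same sum or microRNA host genes kept (the last added after seeing the data). With host genes kept its median was unchanged and only the random lists differed (percentile 2.435), so that case shows no effect of processing on the list. With no filter on low values its median was 0.00, at percentile 42.5. Of the 5, UGT2B28 (-0.41), UGT2B11 (-0.35) and UGT2B15 (-0.22) are close paralogs that can share reads.

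AKR1C3 stood at 1.27 FPKM in the DMSO library and 1.55 FPKM in the Indocin library (0.17). Its close paralogs, which can share reads with it, were listed at 0.291 and 1.33 FPKM for AKR1C1 (0.85) and at 0.315 and 0.735 FPKM for AKR1C2 (0.40), both under the minimum mean, and AKR1C4 was listed at 0 in both libraries. Of 24 steroid synthesis genes 10 reached the minimum mean, and none of them differed by 1.5-fold. The largest difference was for the reductase SRD5A3 (12.1 and 16.7 FPKM, 0.43), and steroid sulfatase, STS, had a ratio of -0.23. The median was -0.11, at percentile 7.73, and with no filter on low values it was 0.02, at percentile 60.9.

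Genes of G1/S and DNA replication were lower in the Indocin library. Cyclin E2, CCNE2, stood at 16.1 FPKM in the DMSO library and 8.0 FPKM in the Indocin library, the ribonucleotide reductase subunit RRM2 at 84.9 and 46.6 FPKM, the replication initiation factor MCM10 at 15.4 and 8.18 FPKM, and the flap endonuclease FEN1 at 81.7 and 48.0 FPKM (-0.76). All 46 listed genes had ratios below 0, and 13 were at least 1.5-fold lower. With the same upper quartile 45 were below 0 and 7 at least 1.5-fold lower, and with the same sum 45 and 8, the DNA polymerase subunit POLE changing sign. The median was -0.47 (quartiles -0.60 and -0.37), at percentile 0. Genes of G2 and mitosis showed smaller differences in the same direction, with CDK1 at 381.4 and 203.6 FPKM (-0.90), UBE2C at 116.5 and 92.3 FPKM (-0.33), CCNA2 at -0.57, AURKB at -0.56 and CDC20 at -0.48. All 45 were below 0 as deposited (44 with the same sum, where CDC25C changed sign), 1 was at least 1.5-fold lower, and the median was -0.33, at percentile 0.

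MYC stood at 113.9 FPKM in the DMSO library and 81.6 FPKM in the Indocin library (-0.48). All 34 genes of the list of MYC targets and ribosome biogenesis had ratios below 0 (33 under each rescaling, where GNL3 changed sign), including TCOF1 (-0.51), NOP16 (-0.45) and PPAN (-0.45). None reached 1.5-fold, and the median was -0.31, at percentile 0. The cell cycle inhibitor CDKN1A stood at 79.0 and 112.4 FPKM (0.50).

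**Figure D2:**
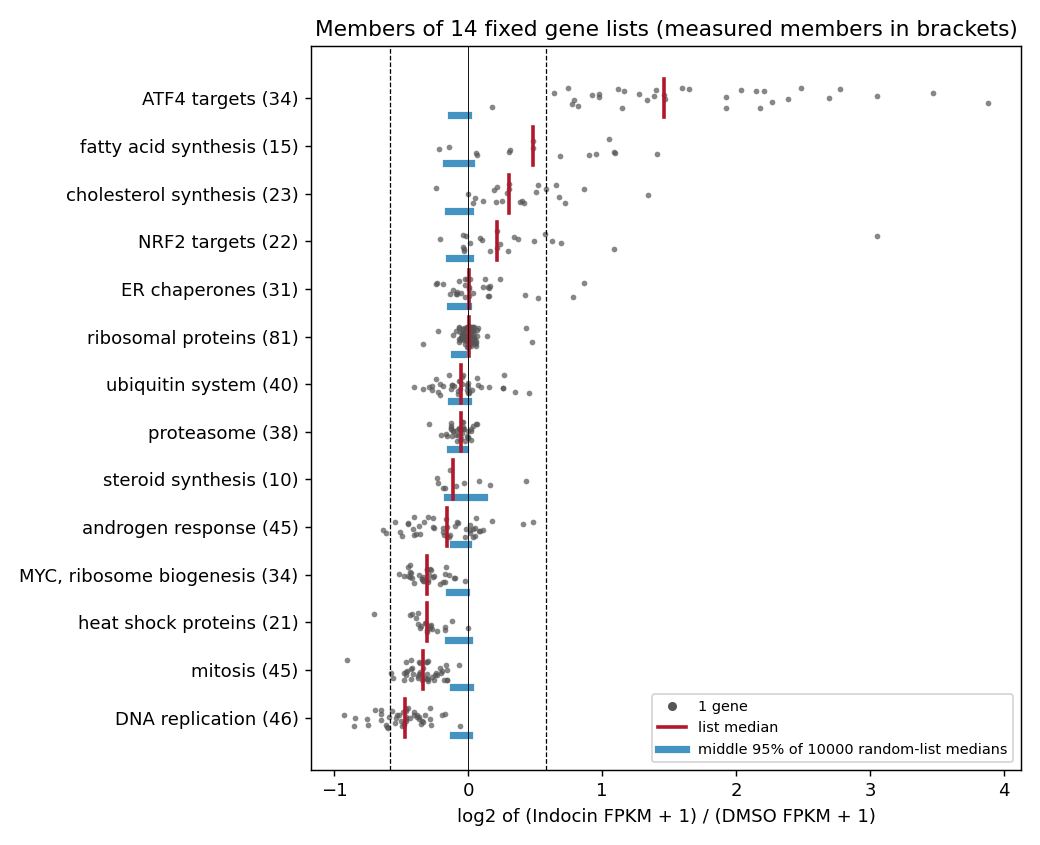
Log2 ratios of Indocin over DMSO for the measured members of 14 gene lists, 1 grey point per gene (vertical scatter within a list is only for display), with the list median in red, the middle 95% of 10000 random-list medians in blue and dashed lines at 1.5-fold. The ATF4 targets lie highest with a median of 1.47 and the DNA replication genes lowest with a median of -0.47, while the proteasome and ubiquitin medians of -0.06 and -0.05 lie within their blue bars.

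Genes of lipid synthesis were higher in the Indocin library. The desaturase SCD stood at 99.9 FPKM in the DMSO library and 267.3 FPKM in the Indocin library (1.41), the lipogenic transcription factor SREBF1 at 89.1 and 192 FPKM (1.10), malic enzyme, ME1, at 19.0 and 41.5 FPKM (1.09), and the acyl-CoA synthetase ACSL1 at 25.4 and 53.7 FPKM (1.05). Of 15 measured genes of fatty acid synthesis 7 were at least 1.5-fold higher and none as much lower, with a median of 0.49, at percentile 100. Among 23 genes of cholesterol synthesis, 5 were at least 1.5-fold higher (8 with the same sum), including the sterol sensor partner INSIG1 (37.3 and 95.8 FPKM), SREBF2 (0.87) and mevalonate kinase, MVK (0.68). The median was 0.31, at percentile 100.

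PPARG, a nuclear receptor of lipid metabolism, stood at 3.82 FPKM in the DMSO library and 5.67 FPKM in the Indocin library (0.47). None of 18 PPAR targets and fatty acid oxidation genes differed by 1.5-fold, with SLC25A20 (-0.38), CPT1A (-0.38) and ETFDH (0.34) the furthest, and the median was 0.01, at percentile 92.4. The cyclooxygenase genes were hardly detected, PTGS1 at 0.252 and 0.202 FPKM and PTGS2 at 0.0608 and 0.0156 FPKM. Of 28 prostaglandin and lipoxygenase genes 8 were measured, and the prostaglandin E synthase PTGES (1.60 and 0.617 FPKM, -0.68) was the only member past 1.5-fold. CBR1 (-0.24) and PTGES3 (-0.23) differed less, and the median was -0.18, at percentile 3 and so inside the middle 95%.

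Antioxidant targets of NRF2 included 4 of 22 measured members at least 1.5-fold higher, SLC7A11, ME1, heme oxygenase HMOX1 (26.0 and 42.6 FPKM, 0.69) and the glutathione synthesis subunit GCLM (21.3 and 33.5 FPKM, 0.63). Their median was 0.22, at percentile 100, and SLC7A11 and ME1 belong to other lists as well. Among 24 p53 targets, 3 were at least 1.5-fold higher, SESN2, the cytokine GDF15 (19.2 and 88.5 FPKM, 2.15) and the pro-apoptotic BBC3 (1.44 and 3.88 FPKM). The p53 median was 0.12, at percentile 99.9, and without members of other lists, such as SESN2 and GDF15, it was 0.07, at percentile 96.6 and so inside the middle 95%. In the apoptosis list PMAIP1, which encodes the pro-apoptotic NOXA (3.80 and 9.50 FPKM, 1.13), and BBC3 were the 2 of 22 members past 1.5-fold, with a median of -0.03, at percentile 50.4. Among 26 genes of autophagy and lysosomes, MAP1LC3B (28.2 and 48.1 FPKM, 0.75) was the only member past 1.5-fold, and the median was 0.06, at percentile 99.9.

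Genes of glycolysis and hypoxia had a median of -0.15 over 30 members, at percentile 0.37 (-0.08 with the same upper quartile or the same sum), with the lactate transporter SLC16A3 at -0.55 and PFKFB3 at -0.53. Of these 24 were below 0 and 6 above (18 and 12 with the same sum), and the angiogenic factor VEGFA, which was higher, was the only member past 1.5-fold (135.4 and 290.3 FPKM, 1.09). The percentile of the glycolysis and hypoxia list was not checked against a trend over transcript length and GC content. The 51 genes of oxidative phosphorylation had a median of -0.04, at percentile 96.3 (0.04 with the same upper quartile or the same sum), and none, ATP5G1 (-0.32) and CYCS (-0.24) included, differed by 1.5-fold. Immediate early genes had a median of -0.21 over 12 members, at percentile 0.21, with JUNB at -0.44 and KLF6 at -0.41, whereas ATF3 was the only member past 1.5-fold and was higher.

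Lists of immune and signalling genes lay inside the middle 95% of random lists. Among 29 interferon-stimulated genes ISG20 (2.41 and 6.29 FPKM, 1.10) and IFI35 (0.64) were at least 1.5-fold higher, with a median of 0.05, at percentile 92.3. The chemokine CCL20 (3.78 and 13.7 FPKM, 1.62) was the only one of 11 NF-kB targets past 1.5-fold, with a median of -0.07, at percentile 19.9. Of 9 Wnt targets none was past 1.5-fold, TCF7 (-0.50) and CCND1 (-0.45) being the lowest besides MYC, with a median of -0.16, at percentile 3.08. This list lay below the middle 95% under 5 of the alternatives. Among 8 genes of drug and dioxin response TIPARP (17.4 and 10.8 FPKM, -0.64) was the only member past 1.5-fold, and it was not past it with the same upper quartile. ABCG2 (1.70 and 0.980 FPKM, -0.45) was past it in FPKM alone. The median was -0.00, at percentile 59.8 (0.07 with the same upper quartile and 0.08 with the same sum).

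Few markers of other cell types were measured. The 9 luminal prostate markers had a median of -0.19, at percentile 3.55 and so inside the middle 95% (-0.01, at percentile 88.3, without members of other lists), with 1 member past 1.5-fold, HOXB13 at -0.45, KRT8 at -0.30 and CDH1 at 0.29. With the same upper quartile or the same sum the median was -0.11 and no member was past 1.5-fold. Only ITGA6 of 9 basal markers was measured (0.17), only COL1A1 of 8 fibroblast markers (0.07), only CD68 of 6 leukocyte markers (-0.13) and 0 of 6 endothelial markers. Of 10 mesenchymal markers 4 were measured, SNAI1 (5.58 and 3.22 FPKM, -0.64), VIM (-0.47), SNAI2 (-0.22) and FN1 (0.00), with a median of -0.34, and SNAI1 was not past 1.5-fold with the same upper quartile. The 3 measured neuroendocrine markers, ENO2 (-0.06), SYT4 (-0.02) and ONECUT2 (-0.09), and the metallothioneins MT1F (0.57), MT1X (-0.11) and MT2A (-0.00) were too few for a percentile.

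Lists that bear on RNA quality differed little between the libraries. Cytosolic ribosomal protein genes had a median of 0.01 over 81 members, at percentile 100 because random lists of like expression had a median of -0.07, and none was past 1.5-fold. RPL21 (0.48), RPL10L (0.43), RPL7L1 (-0.34) and RPS26 (-0.22) were the furthest from 0, and RPL21, RPL10L and RPS26 have near-identical copies or pseudogenes. Histone genes with HIST symbols, many but not all of which make mRNA without a poly(A) tail, had a median of -0.00 over 29 members, at percentile 41.9. HIST1H2AK (0.96) and HIST1H3E (0.73) were past 1.5-fold. Genes of the mitochondrial genome matched 0 symbols and were not analysed here.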

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

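The test in this part was chosen only after the result was seen. Among the short RNA genes (microRNA host transcripts not counted) kept out of the comparison, 6 were listed at 0 in the DMSO library and at 10 FPKM or more in the Indocin library: the microRNA gene MIR3936 at 208.6 FPKM, the small nucleolar RNA genes SNORA72 at 43.9 FPKM, SNORA9 at 21.6 FPKM and SNORA48 at 16.1 FPKM, the Cajal body RNA gene SCARNA14 at 18.2 FPKM and the spliceosomal RNA gene RNU11 at 15.5 FPKM. No fold is given against a value of 0. Values at 0 in the Indocin library only were more common, for example for MIR941-1 and RNU12, at 63.2 and 7.41 FPKM in the DMSO library. Of 75 short RNA genes with a mean of at least 1 FPKM, 13 were at least 2-fold higher in the Indocin library and 37 at least 2-fold lower, and 9 were under 0.01 FPKM in the DMSO library against 27 in the Indocin library. The SNORA genes, which guide pseudouridylation of other RNAs, numbered 45, of which 8 were higher and 24 lower, and 4 were under 0.01 FPKM in the DMSO library against 19 in the Indocin library. The 4 SNAR genes summed to 802.8 FPKM in the DMSO library and 216.6 FPKM in the Indocin library.

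Unstable FPKM estimates at lengths near the fragment length are a candidate explanation for the values at 0. Among short RNA genes with a mean of at least 2 FPKM, 47.1% (32 of 68) were under 0.01 FPKM in 1 library, against 0 of 10672 other genes over the same range of means. This comparison restates the pattern that prompted it and decides nothing between explanations. Unstable estimates, a difference in how much short RNA each library retained and an effect of Indocin on these RNAs all stay open with 1 library per group.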

How the results depend on the processing

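The removal of a length, GC and expression trend and the keeping of microRNA host genes were chosen only after seeing the data, and the other alternatives were planned. Counts of genes moved by more than 1.5 times in these cases: 262 higher and 90 lower at a 1.5-fold threshold, 41 higher and 0 lower with a pseudocount of 5 FPKM, 22 lower with a pseudocount of 0.1 FPKM, 3 lower with a mean of at least 5 FPKM, and 42 lower with short RNA genes kept. A lower threshold or pseudocount raises these counts and a higher pseudocount or minimum lowers them by construction, and the 42 include the short RNA genes themselves. The other 13 alternative counts stayed within 1.5 times of 90 higher and 5 lower. For the 10 lists that answer the comparison, 101 alternative values kept their direction against random lists and their side of the middle 95% (after trend removal only the sign of the median was compared), and 1 turned within it (steroid synthesis with no filter on low values, 0.0157, which adds genes under the minimum mean). For the other lists 186 values kept both, 5 turned direction inside the middle 95% (luminal markers, genes of drug and dioxin response and apoptosis genes without members of other lists, and apoptosis genes and histones with a mean of at least 5 FPKM), 8 newly passed (5 of them Wnt targets and 3 androgen-repressed genes) and 1 no longer passed (p53 targets without members of other lists, 0.07). With microRNA host genes kept, the androgen-repressed median was unchanged and only the random lists differed. For single named genes 395 values kept direction and side of 2-fold, 5 newly passed with a pseudocount of 0.1 FPKM and 7 no longer passed, 5 of them with a pseudocount of 5 FPKM and 2 for DUSP2 under rescaling, and none changed direction past the threshold. Rescaling moved the median of all genes from -0.03 to 0.04 or 0.05. Leaving out genes with more than 1 line removed no gene, so it gave no value. No replicate could be left out, no paired analysis was possible because each group had 1 library, and the read depth that limits low genes is unknown.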

Other observations

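The 5 gene lists of this part, the chaperone test and the tests on cultures were chosen only after the results were seen, and the trend removal was added after the data were examined with its bounds written before its result. Enzymes that charge cytosolic tRNAs had a median log2 ratio of 0.51 over 20 genes, at percentile 100. Of these, 8 were at least 1.5-fold higher and none as much lower, led by GARS (75.8 FPKM in the DMSO library and 210.5 FPKM in the Indocin library, 1.46), CARS (1.39), SARS (1.14) and AARS (0.98). Of the 20 genes 13 were above 0 and 7 below (14 and 6 with the same sum), the lowest being FARSA (-0.34) and FARSB (-0.30), which form the phenylalanine enzyme. A list of 17 mitochondrial enzymes had a median of -0.07, at percentile 35.5 (0.00 with the same upper quartile), with none past 1.5-fold. That list has no separate entry for GARS or KARS, so the 2 lists do not match gene for gene. Amino acid transporters had a median of 0.31 over 20 genes, at percentile 100, with 8 at least 1.5-fold higher, including SLC1A4 (1.79 and 11.6 FPKM, 2.17), SLC7A5 (1.16) and SLC1A5 (0.97). Of these 14 were above 0 and 6 below, the lowest being SLC1A3 (2.15 and 1.11 FPKM, -0.58). With the same sum, where the pseudocount weighs less, 1 transporter was at least 1.5-fold lower, against 0 with the same upper quartile. Genes of serine synthesis and one-carbon metabolism had a median of 0.46 over 14 genes, at percentile 100, with 7 at least 1.5-fold higher, including PSAT1 (86.9 and 332.4 FPKM, 1.92), MTHFD2 (1.12) and PHGDH (0.82), while TYMS, which makes thymidylate for replication, stood at -0.48. Of these lists, 4 synthetase genes, 4 transporters and 7 serine or one-carbon genes also belong to other lists, mostly ATF4 targets, so they are not independent of that result.

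Tubulins were lower in the Indocin library, with a median of -0.33 over 15 genes, at percentile 0. TUBA3D, TUBA3E and TUBA4A (136.5 and 83.1 FPKM, -0.71) were at least 1.5-fold lower, and the abundant TUBB (1009 and 734.2 FPKM, -0.46) and TUBA1B (1208 and 880.5 FPKM, -0.46) stood closer to 0. TUBA1A (0.23) was 1 of 3 tubulins above 0. Other genes in no fixed list that were higher in the Indocin library were the peptide hormone ADM2 (13.0 and 51.0 FPKM, 1.89), transglutaminase TGM1 (1.84), fucosyltransferase FUT3 (1.75), the glucocorticoid-induced TSC22D3 (18.9 and 62.2 FPKM, 1.67) and the iron-carrier protein LCN2 (1.38).

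The ATF4 target list had a median log2 ratio of 1.47. Removing the trend over transcript length, GC content and expression left a median of 1.54, with a lower quartile of 1.07. The fitted trend had a standard deviation of 0.059 across genes, too small for a difference of this size. That small size argues against the trend as the cause of the higher list. Its removal could hardly have come out otherwise and adds little. ER stress as a cause stays open, since its only test was the ER chaperone list (upper quartile 0.15, percentile 98.3, 17 members above 0 and 14 below, HERPUD1 at 0.86 and XBP1 at 0.78), whose values were already seen. A difference between the 2 cultures other than the compound cannot be told apart from it, because there was 1 library per group.

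The DNA replication list and the androgen response list were both lower in the Indocin library. After removal of the same trend the replication median was -0.47 with an upper quartile of -0.36. Here too the small size of the trend argues against it as the cause, and its removal could hardly have come out otherwise. The androgen response median over the 42 of 45 members with a length and GC value was -0.16 before removal and -0.0927 after it, at percentile 0.77 and so still outside the middle 95%. Part of the lower median thus went with the fitted trend. The bound set on their upper quartile was missed before removal (0.03) as well as after (0.04), so the test does not decide whether the trend accounts for the lower list. Slower proliferation after Indocin is a candidate explanation for the replication genes, and it was not tested against cell numbers. A difference between the 2 cultures other than the compound, such as density at harvest, stays open with 1 library per group.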
